A study of Mus musculus with 14 samples.

How the data were processed

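RNA was measured by sequencing in whole liver from 14 mice kept on normal chow, littermates that the labels class by Pkd1 genotype as WT (6 libraries), Het (4 libraries) and Homo (4 libraries), each with Cre in the label. Per the labels' protocols, RNA was extracted with Trizol and an RNeasy column and libraries were made with a NuGen Ovation mouse RNA-seq kit. The deposited table held estimated counts per Ensembl gene, which the authors made with tools listed as STAR and Salmon on the build GRCm39, per the submitters' processing notes. The role of each tool, the versions, the annotation release, trimming and the use of strand are not given in the sources used here. The table had 57180 genes and 1 column per library, with no pooled column and no entry that named no gene. Columns were tied to samples by the sample description, and gene symbols came from the table itself. Between 6.36% and 8.59% of the values per library were not whole numbers (tolerance 0.01), and all values were rounded to whole counts before testing.

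Total counts per library ran from 18573739 to 40925973. No pair of libraries held identical values, and the counts of the closest pair differed by far more than sampling noise (chi-square per degree of freedom 26.4), so each library counted as 1 replicate. The labels give 1 numbered mouse per library. They give no litter, sex, age, collection time or sequencing batch. Y-linked transcripts were present in all 14 libraries and Xist had at most 12 counts in any, so no sex term could be fitted.

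Genes with enough counts were kept with the filterByExpr function of edgeR 4.0.16 (count minimum 10, total minimum 15), which left 16201. Counts were scaled with TMM factors and are given as CPM, counts scaled to the effective library size. All 14 libraries entered a single quasi-likelihood fit (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with a contrast for Homo against WT, Het against WT and Homo against Het, and a second fit with genotype as a step of 0, 1 and 2 for the trend over WT, Het and Homo. P-values were adjusted with Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard errors (SE), group levels as mean ± SD over libraries. Fold intervals are at 95%. Single values were compared between groups with exact permutation tests, two-sided. Counting floors of 3 counts, taken over the group, cover counting error only.

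Of 31 gene lists fixed before the data were examined, 28 had at least 5 measured members and were tested with camera in limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2. They covered fatty acid oxidation (PPARalpha), cholesterol synthesis (SREBP2), lipogenesis (SREBP1c), bile acid and transport, xenobiotic metabolism, glucose metabolism, oxidative phosphorylation, ribosomal proteins, the amino acid response (ATF4), the ER unfolded protein response, heat shock chaperones, the acute phase, the interferon response, immediate early genes, the circadian clock, the cell cycle, YAP targets, polycystic disease and cilium, male-biased and female-biased liver genes, pericentral and periportal hepatocytes, and markers of cholangiocytes, stellate cells, Kupffer cells, sinusoidal endothelium, lymphocytes and erythroid cells. The lists for neutrophils (4 measured members), pancreas (2) and adipose tissue (3) were not tested. Each list was also tested with an estimated correlation, with fry, and by exact permutation of its mean log2 CPM per library.

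Genes to be named were chosen by a rule fixed at the same time. It took Pkd1, Tsc2 and Pkd2 always. For Homo and for Het against WT, the 10 largest rises and falls past the threshold were added, and for Homo against Het and the trend the 5 largest each way, among genes of at least 1 CPM that are not model names or pseudogenes. Where fewer than 10 passed, genes with the smallest p filled the number to 10. From each called list the 4 members with the smallest p were taken, and from lipogenesis, the ATF4 response, the cell cycle and cholangiocytes the 3 with the smallest p in Homo against WT. Some genes that the rule picks are not reported here. Any other gene named was chosen after its values were seen.

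Gene places came from GENCODE M21 (GRCm38), a different build from the GRCm39 of the table, so only chromosomes and the order of genes along them were used. Of the genes tested, 15613 had a place. Transcripts of called genes off chromosome 17 were compared with transcripts of tested chromosome 17 genes using BLAST 2.17.0 (at least 90% identity over at least 50% of the query).

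The fit was tested on simulated counts drawn from the real means, spreads and library sizes, over 15826 genes that passed the filter there. For Homo against WT it recovered 47.1% of 68 genes changed 1.5-fold, 56.2% of 64 changed 2-fold and 93.1% of 58 changed 4-fold, with 2 unchanged genes called. With genes in Het at the middle of the 2 doses, Het against WT recovered 4.41%, 23.4% and 67.2% of those genes, and Homo against Het 0%, 6.25% and 55.2%. The trend recovered 48.5%, 57.8% and 94.8%. A simulated list shift of -0.50 on the log2 scale was called by camera with the preset and with the estimated correlation and by fry, with no other list called. Genes were drawn independently there, while the estimated correlation in the real data was 0.26 for fatty acid oxidation and 0.51 for heat shock chaperones. The simulation therefore does not show how these tests behave on correlated lists. The permutation of list means was not simulated.

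Alternatives were DESeq2 1.42.0, limma voom with quality weights, robust edgeR, RLE scaling, the library total alone, no low-count filter, a stricter filter (1 CPM in at least 6 libraries), the replicate number as a block, 1 surrogate variable from sva 3.50.0, fits of only the groups compared, and leaving out each library. Leaving out chromosome 17 genes and the permutation of list means were added after the data had been seen.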

Results

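Livers of 6 WT, 4 Het and 4 Homo littermates for Pkd1, the gene of polycystin 1, were profiled by RNA sequencing on normal chow. The question was how the liver transcriptome differed from WT in the genotypes labelled Het and Homo. The labels give neither the Pkd1 allele nor the Cre driver, so the cells in which Pkd1 was altered are not known. Total counts per library ran from 25238140 to 40925973 in WT, from 22833853 to 26245475 in Het and from 18573739 to 28431875 in Homo. The exact permutation p for the totals against WT was 0.0619 in Het and 0.133 in Homo. The mitochondrial percentage of counts was 11.1 ± 0.84 in WT, 10.6 ± 0.569 in Het and 11.1 ± 0.222 in Homo (SD).

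Pkd1 transcripts (ENSMUSG00000032855, chromosome 17) were lower in Homo livers. The level was 34.8 ± 2.77 CPM in WT (SD, n = 6), 32.2 ± 3.52 CPM in Het (n = 4) and 25.3 ± 1.51 CPM in Homo (n = 4). Each Homo library, from 23.1 to 26.4 CPM, lay below each WT library, from 31.4 to 37.7 CPM. The fold in Homo over WT was 0.728 (95% interval 0.646 to 0.819, log2 -0.46, SE 0.0802, edgeR adjusted p = 0.0246), and the exact permutation p of 0.00476 was the smallest the design allows. In Het the fold was 0.927 (interval 0.825 to 1.04, edgeR adjusted p = 0.998, exact permutation p = 0.21). Homo and Het differed by a fold of 0.785 (edgeR adjusted p = 0.916, exact permutation p = 0.0286, the smallest 4 against 4 allow). These counts cover the whole gene, so reads outside any deleted exons are included, and bulk liver does not resolve which cells carry the change. The adjusted p in Homo went above the threshold with the library total alone (0.0576), with 1 surrogate variable (0.0572), and without WT 3 (0.0713), WT 4 (0.0753), WT 6 (0.058), Homo 1 (0.131), Homo 2 (0.0677), Homo 3 (0.083) or Homo 4 (0.0567). It was also above the threshold with the replicate number as a block (0.071), although those numbers did not pair the libraries.

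The neighbour of Pkd1, Tsc2, a subunit of the complex that restrains mTORC1, was at 46.9 ± 3.02 CPM in WT, 43.8 ± 1.63 CPM in Het and 40.3 ± 2.14 CPM in Homo (SD, n = 6, 4 and 4). Its difference in Homo missed the threshold (log2 -0.22, SE 0.0613, edgeR adjusted p = 0.51), while the exact permutation p for Tsc2 alone was 0.00952. Pkd2, which encodes the channel partner of polycystin 1, stood at 19.3 ± 3.42, 12.8 ± 3.77 and 15.2 ± 6.84 CPM, with edgeR adjusted p = 0.998 against WT for both genotypes. The Pkd2 fold in Het over WT was 0.661 (95% interval 0.44 to 0.992, exact permutation p = 0.0286), and in Homo over WT 0.786 (interval 0.526 to 1.17, exact permutation p = 0.21).

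**Figure D1:**
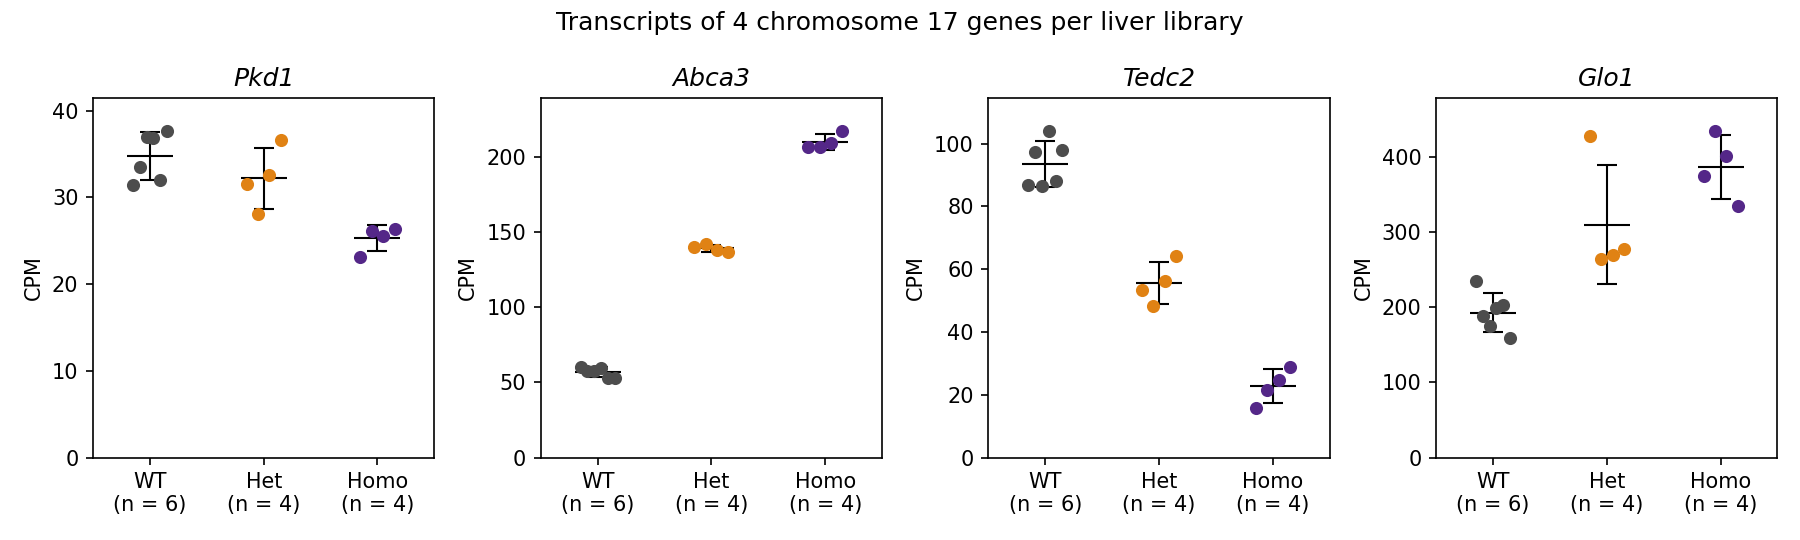
CPM of Pkd1, Abca3, Tedc2 and Glo1 (vertical axes, from 0) in each library of the WT, Het and Homo groups (points), with the group mean and SD (bars). Pkd1 averaged 34.8, 32.2 and 25.3 CPM, and Abca3 averaged 56.9, 139 and 210 CPM over WT, Het and Homo.

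In Homo against WT, 36 of 16201 genes passed, 26 higher and 10 lower, and 28 of the 34 with a known place were on chromosome 17, where Pkd1 lies. Of the 26 higher genes, Glo1, a glyoxalase that detoxifies methylglyoxal, had the highest level, at 193 ± 26.1 CPM in WT and 387 ± 42.2 CPM in Homo (SD, log2 1.00, edgeR adjusted p = 0.0027). Abca3, a lipid transporter of lamellar bodies, rose from 56.9 ± 3.22 to 210 ± 5.16 CPM (log2 1.88, SE 0.0542, edgeR adjusted p = 2.04e-11). Tedc2, a component of centriole assembly, fell from 93.5 ± 7.33 to 22.8 ± 5.44 CPM (log2 -2.04, SE 0.139, edgeR adjusted p = 1.02e-06). Riok2, a kinase of ribosome maturation, fell from 25.4 ± 1.56 to 12.7 ± 1.19 CPM (log2 -1.0, edgeR adjusted p = 2.58e-06).

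Several of the other risers were class I-like histocompatibility genes. H2-Bl went from 1.15 ± 0.416 to 10.4 ± 4.00 CPM, H2-T10 from 1.15 ± 0.424 to 3.53 ± 1.08 CPM and H2-T24 from 3.13 ± 0.756 to 9.03 ± 2.18 CPM (SD, n = 6 and 4). These genes are close relatives of one another, so the division of reads among them is uncertain. Meiob, a meiotic recombination factor, rose by log2 1.47, the dynein light chain genes Dynlt1b and Dynlt2a2 by 1.46 and 1.18, the plasma phospholipase gene Pla2g7 by 1.40 and the ring finger gene Rnf39 by 1.17. Among the lower genes, Decr2, a peroxisomal enzyme of unsaturated fatty acid oxidation, fell from 117 ± 14.0 to 72 ± 10.7 CPM, and Gfer, a sulfhydryl oxidase of mitochondrial import, from 25.5 ± 2.55 to 17 ± 1.45 CPM. Unkl (log2 -0.82), Pgap6 (-0.71) and Zfp943 (-0.58) were also lower. All genes of this paragraph lie on chromosome 17.

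On other chromosomes, 6 placed genes passed, and 2 more had no place in the annotation used. Hmga1b, a copy of the chromatin protein gene Hmga1, was at 1.27 ± 0.697 CPM in WT and 5.04 ± 1.77 CPM in Homo. Cyp4a12b, a male-biased cytochrome P450, fell from 73.8 ± 11.3 to 37.1 ± 8.53 CPM (log2 -1.0, SE 0.181, edgeR adjusted p = 0.0297). Its close relative Cyp4a12a, looked up after that result was seen, stood at 386 ± 158 and 461 ± 75.8 CPM. The other 4, also named after their values were seen, were the pseudogenes Glo1-ps, Atp6v0c-ps2 and Rnps1-ps, all higher in Homo, and Gm13169. Gm13169 had no count in any Homo library and was at least 22-fold lower than in WT against a floor of 3 counts over the group. Counts of Hmga1b, Glo1-ps, Atp6v0c-ps2 and Rnps1-ps are uncertain because each matched a chromosome 17 transcript at 99.4% identity or more, and the division of reads between Cyp4a12a and Cyp4a12b is uncertain too.

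The number past the threshold was 23 without Homo 1, 64 with DESeq2 (39 higher and 25 lower), and 5 when chromosome 17 genes were left out before adjustment. Leaving those genes out also ended the calls of Hmga1b, Cyp4a12b and the unplaced ENSMUSG00000121610. These passed only when chromosome 17 genes entered the adjustment. Leaving out any 1 library except Het 1 ended the call of at least 1 of Hmga1b, H2-T10, Rnf39, Cyp4a12b, Pgap6, Decr2 and Zfp943, whose highest adjusted p over all alternatives were 0.408, 0.172, 0.282, 0.167, 0.126, 0.0669 and 0.283. The call of Pla2g7 ended with 1 surrogate variable.

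**Figure D2:**
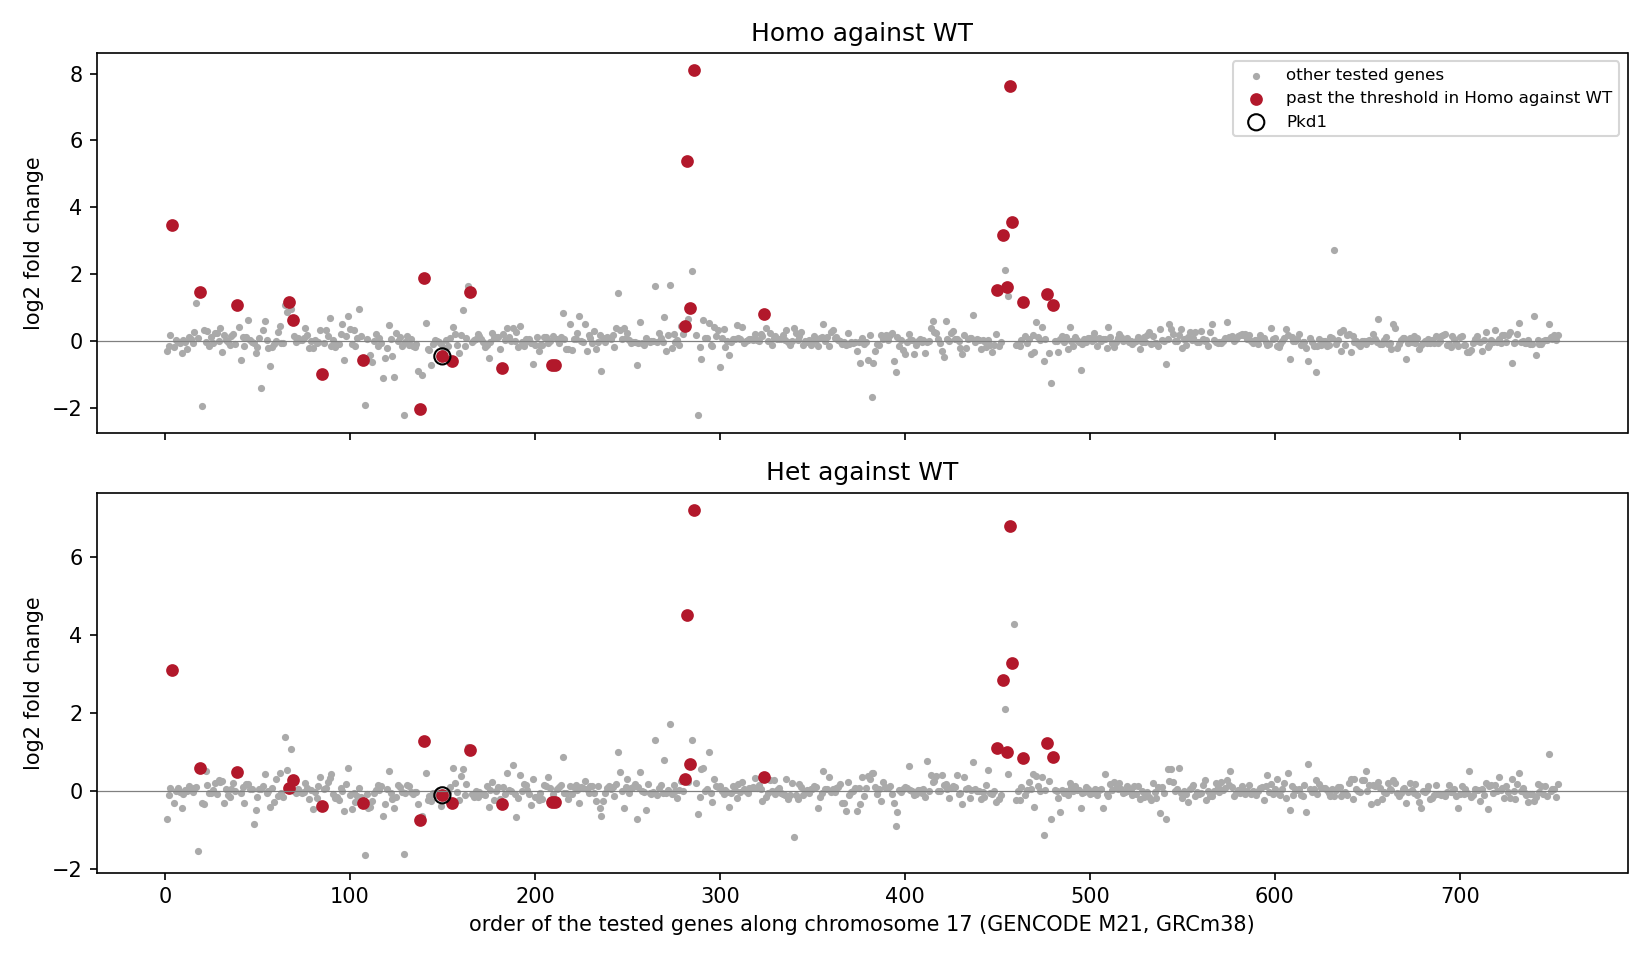
Log2 fold change (vertical axes) of each tested gene along chromosome 17 (horizontal axis, order of the 753 tested genes in GENCODE M21, GRCm38) in Homo against WT (top) and Het against WT (bottom), with the 28 genes past the threshold in Homo in red and Pkd1 circled. The red points run from place 4 to place 480, on both sides of Pkd1 at place 150, and fitted values of genes near 0 counts in WT depend on the prior count.

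In Homo against WT camera called 10 of 28 lists, 6 higher and 4 lower, but none held with an estimated correlation (smallest adjusted p = 0.354). Of all list members, 1 passed over all genes in this comparison, the male-biased gene Cyp4a12b.

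Genes of fatty acid oxidation driven by PPARalpha lay lower in Homo: 23 of 24 measured members had a fold below 1, the median log2 fold change was -0.20, and 0 passed over all genes and 0 adjusted over the list alone. The camera adjusted p was 1.03e-10, and the adjusted p was 0.354 with an estimated correlation. Acaa1b was at 300 ± 80.7 CPM in WT and 209 ± 36.1 CPM in Homo (edgeR adjusted p = 0.943). Acadm was at 125 ± 9.87 and 110 ± 3.25 CPM, and Decr1 at 77.1 ± 2.68 and 67.9 ± 3.71 CPM. The list mean per library differed by -0.40 on the log2 scale (exact permutation p = 0.0476 before adjustment over the 28 lists, n = 4 and 6).

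Genes of cholesterol synthesis driven by SREBP2 lay higher, with 21 of 24 members above 1, a median log2 fold change of 0.19, 0 past the threshold over all genes and 2 adjusted over the list alone (camera adjusted p = 1.39e-06, adjusted p = 0.354 with an estimated correlation). Dhcr7, the last enzyme of the pathway, was at 69.2 ± 7.14 CPM in WT and 88.2 ± 7.13 CPM in Homo, and Acat2, which lies on chromosome 17, at 36.1 ± 3.70 and 55.2 ± 5.21 CPM (edgeR adjusted p = 0.274 and 0.0761). Cyp51 was at 140 ± 10.4 and 170 ± 19.7 CPM, and Fdps at 172 ± 28 and 226 ± 48.9 CPM.

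Protein-folding genes lay lower. Of the heat shock chaperones 15 of 16 were below 1 (median log2 -0.28, camera adjusted p = 1.62e-07, adjusted p = 0.354 with an estimated correlation). Of these 16 genes, 3 lie on chromosome 17. Hsp90aa1 was at 241 ± 54.5 CPM in WT and 166 ± 37.5 CPM in Homo, Hsph1 at 102 ± 22.2 and 72.4 ± 14.2 CPM. Dnaja1 was at 356 ± 32.9 and 291 ± 57.5 CPM, and Hspa1b at 38.1 ± 8.93 and 25.1 ± 4.83 CPM. Of the ER unfolded protein response genes 17 of 20 were below 1 (median log2 -0.09, camera adjusted p = 0.000635, adjusted p = 0.423 with an estimated correlation). The ER chaperone gene Hspa5 was at 616 ± 52.4 and 522 ± 58.4 CPM, Creld2 at 50.2 ± 8.33 and 34.4 ± 9.76 CPM. Hyou1 was at 227 ± 23.8 and 192 ± 23.3 CPM, and Hsp90b1 at 754 ± 55.2 and 680 ± 19.0 CPM. In both lists 0 members passed, over all genes or adjusted over the list alone. Xenobiotic metabolism was the fourth list called lower, with 20 of 24 below 1 and 0 past the threshold (camera adjusted p = 0.00563, adjusted p = 0.354 with an estimated correlation). Its named members were Aldh1a1 (392 ± 38.7 and 337 ± 35.9 CPM), Nqo1 (1.79 ± 0.432 and 1.17 ± 0.471 CPM), Gsta2 (5.56 ± 1.44 and 4.07 ± 1.01 CPM) and Abcb1a (3.74 ± 0.833 and 2.84 ± 1.04 CPM). The ER call ended without Homo 1 (camera adjusted p = 0.0506) and the xenobiotic call without Homo 2 (0.189). Without Homo 1 the ER list mean differed by -0.06 in place of -0.12. In place of -0.19, the xenobiotic list mean differed by -0.29 without Homo 1 and by -0.11 without Homo 2.

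Cell cycle genes lay higher in Homo in 22 of 24 members (median log2 0.26, camera adjusted p = 0.000319, adjusted p = 0.354 with an estimated correlation), with 0 past the threshold. The replication helicase genes Mcm5 and Mcm2 were at 2.59 ± 0.337 and 3.04 ± 0.352 CPM in WT and 3.56 ± 0.537 and 4.20 ± 0.616 CPM in Homo, and the proliferation marker Mki67 at 5.52 ± 1.58 and 7.60 ± 1.70 CPM. Cdkn1a, a brake on the cycle, was at 1.25 ± 0.408 and 3.96 ± 5.50 CPM, and without Homo 4 its log2 fold change was -0.03. Without Homo 4 the list mean differed from WT by 0.11 in place of 0.24 on the log2 scale, and the call ended (camera adjusted p = 0.122). Ribosomal protein genes were above 1 in 53 of 67 members at a median log2 of 0.07 (camera adjusted p = 1.68e-05, adjusted p = 0.423 with an estimated correlation, 0 members past the threshold). Rps15 was at 117 ± 6.32 and 135 ± 14.3 CPM. Rpl13 was at 272 ± 8.93 and 297 ± 8.20 CPM, and Rplp0 at 191 ± 14.0 and 212 ± 13.0 CPM. Without Homo 3 the difference of the ribosomal list mean was 0.04 in place of 0.06 (camera adjusted p = 0.0208).

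Markers of resident macrophages were above 1 in 16 of 19 members (median log2 0.17, camera adjusted p = 0.000116, adjusted p = 0.354 with an estimated correlation). C1qb was at 30.3 ± 2.39 CPM in WT and 35.3 ± 1.48 CPM in Homo, Clec4f at 58.2 ± 4.54 and 65.2 ± 5.37 CPM. Cd5l was at 48.3 ± 8.62 and 57.5 ± 1.37 CPM, and Cd68 at 7.57 ± 1.36 and 9.63 ± 0.630 CPM. Lymphocyte markers (10 of 13 above 1, camera adjusted p = 0.0232, adjusted p = 0.354 with an estimated correlation) included Cd3e, at 11.7 ± 3.87 and 18.5 ± 3.43 CPM and Igkc at 3.76 ± 1.55 and 4.93 ± 1.2 CPM, while Ltb stayed under 1 CPM. Interferon response genes (16 of 22 above 1, camera adjusted p = 0.00911, adjusted p = 0.492 with an estimated correlation) included Oas1a at 3.03 ± 0.639 and 4.34 ± 0.867 CPM and Oas2 at 4.45 ± 0.481 and 5.43 ± 0.632 CPM. Cmpk2 was at 3.42 ± 0.433 and 4.30 ± 0.414 CPM. In these 3 lists 0 members passed, over all genes or adjusted over the list alone. The lymphocyte call ended without WT 3, WT 4, WT 5, Homo 1 or Homo 2 (camera adjusted p = 0.118, 0.112, 0.0939, 0.0793 and 0.177). The interferon call ended without WT 3, WT 6, Homo 2 or Homo 3 (0.0626, 0.0821, 0.0901 and 0.233). In place of 0.12, the interferon list mean differed by 0.20 without Homo 4 and by 0.07 without Homo 3.

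The remaining lists were not called in Homo against WT. Camera adjusted p were 0.796 for cholangiocytes, 0.931 for polycystic disease and cilium, 0.575 for YAP targets, 0.347 for stellate cells, 0.061 for sinusoidal endothelium, 0.061 for erythroid cells, and 0.974 for lipogenesis. They were 0.179 for the ATF4 response, 0.121 for bile acid and transport, 0.0573 for oxidative phosphorylation, and 0.874 for the acute phase. They were 0.933 for immediate early genes, 0.636 for the circadian clock, 0.663 for glucose metabolism, 0.363 for male-biased and 0.753 for female-biased genes, 0.0972 for pericentral and 0.753 for periportal hepatocytes. The clock list mixes morning and evening genes, so a directional test can miss a shift of phase. Adjusted over the list alone, 1 male-biased and 1 pericentral gene passed. The median, mean and camera direction differed in sign for the acute phase, female-biased, glucose, polycystic, cholangiocyte, stellate and clock lists. Among cholangiocyte markers Sox9 was at 7.39 ± 2.54 CPM in WT and 5.74 ± 1.15 CPM in Homo, Krt7 at 0.49 ± 0.25 and 0.79 ± 0.353 CPM and Anxa13 at 0.332 ± 0.209 and 0.199 ± 0.128 CPM. Among lipogenic genes Slc25a1 was at 141 ± 12.9 and 155 ± 4.46 CPM, Acss2 at 105 ± 17 and 123 ± 32.2 CPM and Fads2 at 673 ± 155 and 587 ± 107 CPM. Of the ATF4 response, Aldh18a1 was at 1.03 ± 0.16 and 1.90 ± 0.47 CPM, Asns at 1.22 ± 0.305 and 1.82 ± 0.833 CPM and Nupr1 at 0.776 ± 0.1 and 0.961 ± 0.244 CPM.

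**Figure D3:**
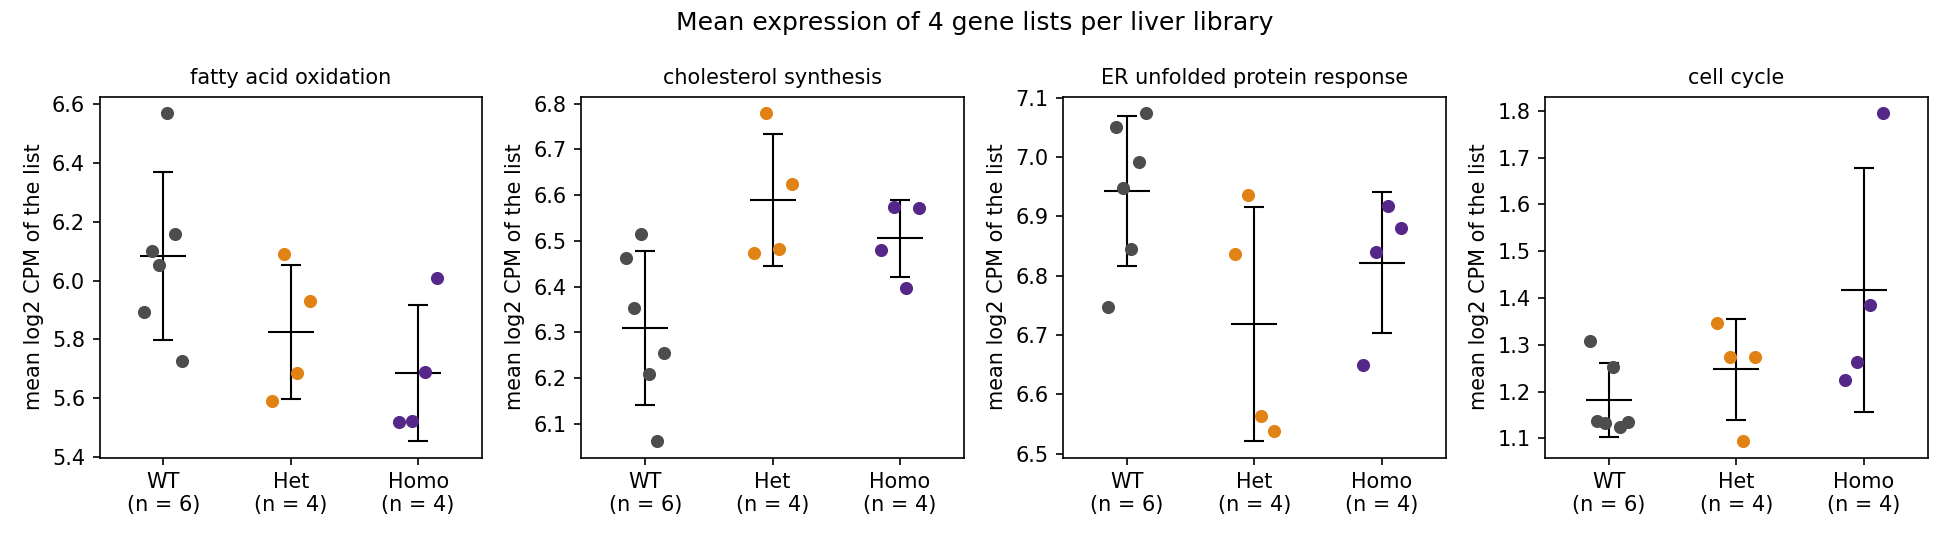
Mean log2 CPM of 4 gene lists (vertical axes, which do not start at 0) in each library of the WT, Het and Homo groups (points), with the group mean and SD (bars). The fatty acid oxidation list differed by -0.40 between Homo and WT, and groups overlapped in all 4 lists.

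In Het against WT, 9 genes passed, all higher, and all 9 also passed in Homo against WT in the same direction, against 0.0144 for independent lists. That value leaves out the shared WT libraries. Unchanged groups simulated against shared WT libraries gave 0 genes called in both comparisons in each of 20 simulations. Those simulations called a mean of 0 genes in Homo and 0.05 in Het against WT. With so few calls an overlap could hardly arise, so they do not measure what the shared WT libraries add. Abca3 rose from 56.9 ± 3.22 to 139 ± 2.34 CPM (log2 1.29, SE 0.054, edgeR adjusted p = 4.75e-09), and H2-Bl from 1.15 ± 0.416 to 8.34 ± 3.26 CPM (log2 2.85, SE 0.333, edgeR adjusted p = 0.000927). The others, named after their values were seen, were Glo1-ps, Atp6v0c-ps2, Rnps1-ps, Gm10503, Gm10499, Gm50252 and ENSMUSG00000121779, which has no symbol. Tedc2, Meiob, Pla2g7, Riok2 and Glo1 had the Homo direction without passing (edgeR adjusted p = 0.0645, 0.0697, 0.0786, 0.0933 and 0.154). Tedc2 stood at 55.5 ± 6.70 CPM and Glo1 at 310 ± 79.3 CPM in Het. Off chromosome 17 the smallest p below the calls belonged to the fibrillar collagen genes Col1a1 (13.4 ± 2.01 and 21.2 ± 3.10 CPM) and Col1a2 (15.5 ± 1.41 and 21 ± 1.67 CPM) and to Wdr59 (9.93 ± 0.565 and 13.1 ± 0.970 CPM), none past the threshold (edgeR adjusted p = 0.0925, 0.0949 and 0.0925). The count was 35 with DESeq2, 27 higher and 8 lower, and 23 without a low-count filter, 20 higher and 3 lower. It was 4 without chromosome 17 genes.

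Camera called 9 lists in Het against WT, 5 higher and 4 lower, and none held with an estimated correlation (smallest adjusted p = 0.454). Without WT 4 the count was 5. Cholesterol synthesis lay higher in 22 of 24 members (median log2 0.28, camera adjusted p = 1.97e-12, adjusted p = 0.454 with an estimated correlation), with 0 past the threshold over all genes and 11 adjusted over the list alone. In Het, Dhcr7 was at 92.0 ± 6.58 CPM, Cyp51 at 182 ± 29.9 CPM. Sqle was at 74.2 ± 17 CPM against 56.2 ± 5.41 CPM in WT, and Acat2 at 48.9 ± 10.9 CPM. All 20 measured genes of the ER unfolded protein response were below 1 (median log2 -0.15, camera adjusted p = 4.32e-08, adjusted p = 0.496 with an estimated correlation, 1 adjusted over the list alone). Hspa5 was at 470 ± 67.0 CPM, Creld2 at 30.6 ± 11.2 CPM. Hyou1 was at 178 ± 34.5 CPM, and Manf at 81.1 ± 16.0 CPM against 103 ± 15.1 CPM in WT.

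Stellate cell genes were above 1 in 14 of 21 members (camera adjusted p = 0.018, adjusted p = 0.666 with an estimated correlation), with 0 past the threshold over all genes and 4 adjusted over the list alone. Beside the collagens Col1a1 and Col1a2, its smallest p belonged to Col3a1 (48.8 ± 6.00 CPM in WT and 63.7 ± 7.16 CPM in Het) and Pdgfrb (8.23 ± 0.524 and 9.84 ± 0.845 CPM). Fatty acid oxidation genes were below 1 in 22 of 24 (median log2 -0.11, camera adjusted p = 0.000216, adjusted p = 0.666 with an estimated correlation). Vnn1 was at 12.9 ± 6.07 CPM in WT and 8.59 ± 2.39 CPM in Het. Acute phase genes were above 1 in 23 of 24 (camera adjusted p = 5.29e-06, adjusted p = 0.666 with an estimated correlation). Haptoglobin, Hp, was at 1770 ± 431 and 2520 ± 1360 CPM, Hpx at 1900 ± 310 and 2580 ± 1010 CPM. Mt1 was at 36.0 ± 48.7 and 111 ± 127 CPM, and Orm3 at 0.905 ± 0.621 and 1.85 ± 0.957 CPM. Het 2 stood apart in this list, at a mean log2 CPM of 8.65 against 6.93 to 7.20 in the other Het libraries. Male-biased genes were above 1 in 15 of 18 (camera adjusted p = 0.00174, adjusted p = 0.496 with an estimated correlation). They include the urinary protein genes Mup11 (6350 ± 998 and 9820 ± 557 CPM), Mup20 (3940 ± 1110 and 5940 ± 1100 CPM) and Mup7 (10000 ± 2610 and 13100 ± 1610 CPM), whose reads are shared among near-identical copies, and Susd4 (20.1 ± 1.66 and 26.1 ± 7.01 CPM). The acute phase call ended without Het 2 (camera adjusted p = 0.327) and the stellate call without WT 2, WT 4, WT 5 or Het 3 (0.104, 0.0515, 0.0625 and 0.163). Without WT 4 the fatty acid list mean differed by -0.16 in place of -0.26 (0.0238).

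Heat shock chaperones were below 1 in 13 of 16 in Het (camera adjusted p = 0.0178, adjusted p = 0.70 with an estimated correlation). Hspa1a was at 3.80 ± 1.94 CPM in WT and 2.03 ± 1.00 CPM in Het, Bag3 at 43.4 ± 3.18 and 36.3 ± 9.04 CPM and Cryab at 1.71 ± 0.429 and 2.12 ± 0.567 CPM. Lipogenic genes were below 1 in 15 of 20 (camera adjusted p = 0.0388, adjusted p = 0.70 with an estimated correlation). Elovl6 was at 250 ± 31.2 and 170 ± 45.1 CPM, Acaca at 255 ± 17.9 and 215 ± 43.4 CPM and Pklr at 369 ± 51.5 and 285 ± 105 CPM, and Pnpla3 at 1.93 ± 0.993 and 0.922 ± 1.18 CPM. Immediate early genes were above 1 in 14 of 16 (camera adjusted p = 0.0388, adjusted p = 0.666 with an estimated correlation). Klf4 was at 1.22 ± 0.294 and 2.17 ± 0.544 CPM, Ier2 at 8.93 ± 1.25 and 10.2 ± 1.53 CPM, Jund at 41.2 ± 3.88 and 44.9 ± 5.15 CPM, and Egr1 lower at 10.2 ± 9.21 and 5.84 ± 3.65 CPM. The heat shock call ended without WT 4, WT 5, WT 6, Het 1 or Het 3 (highest camera adjusted p = 0.407), the lipogenic call without any of WT 1 to WT 5 or Het 1 to Het 3 (0.327), and the immediate early call without Het 2, Het 3 or any WT library except WT 5 (0.391). Without Het 2 the heat shock list mean differed by -0.29 in place of -0.17, without Het 4 the lipogenic one by -0.35 in place of -0.22, and without WT 5 the immediate early one by 0.30 in place of 0.19. Other libraries moved them the other way. The heat shock list mean differed by -0.08 without Het 1 and -0.09 without Het 3. The lipogenic one differed by -0.14 without Het 3, and the immediate early one by 0.06 without Het 2.

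Homo and Het livers differed at 5 genes, 2 higher and 3 lower in Homo, and 4 of them lie on chromosome 17. Abca3 rose from 139 ± 2.34 CPM in Het to 210 ± 5.16 CPM in Homo (edgeR adjusted p = 0.00107), and Dynlt2a2 from 3.28 ± 0.763 to 7.02 ± 0.672 CPM (edgeR adjusted p = 0.0331). Tedc2 fell from 55.5 ± 6.70 to 22.8 ± 5.44 CPM (edgeR adjusted p = 0.0019) and Riok2 from 19.6 ± 1.06 to 12.7 ± 1.19 CPM (edgeR adjusted p = 0.00636). The fifth, Gm13169 on chromosome 4, was named after its value was seen and was at least 21.6-fold lower against the floor of 3 counts. Cyp4a12b (84.4 ± 21.6 and 37.1 ± 8.53 CPM), Dynlt1b, Aldh1a1, Albfm1, Iffo2 and Naa12 came next and did not pass (edgeR adjusted p = 0.0566, 0.403, 0.403, 0.675, 0.744 and 0.744). DESeq2 called 22 genes. A fit of only these 8 libraries called 2, both higher in Homo, of which Abca3 was 1, and ended the other 4 calls (adjusted p = 0.086 for Tedc2). Dynlt2a2 also missed the threshold without WT 2, WT 4, WT 6, Het 2, Het 3 or any Homo library (highest adjusted p = 0.4).

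Camera called 11 lists between Homo and Het, 5 higher and 6 lower in Homo, and none held with an estimated correlation (smallest adjusted p = 0.528). The count was 6 without Het 2 and 6 without Homo 1. Ribosomal protein genes were above 1 in 62 of 67 members (camera adjusted p = 1.25e-05), interferon response genes in 19 of 22 (0.000135), cell cycle genes in 17 of 24 (0.0172), lymphocyte markers in 11 of 13 (0.019) and macrophage markers in 16 of 19 (0.0439). Their adjusted p with an estimated correlation were 0.528 for the first 4 of these lists and 0.635 for macrophages. Ccl5, a T cell chemokine, was at 0.521 ± 0.223 CPM in Het and 1.19 ± 0.297 CPM in Homo. Acute phase genes were below 1 in 23 of 24 (camera adjusted p = 0.000242), xenobiotic metabolism in 19 of 24 (0.0125), erythroid markers in 5 of 6 (0.0172), fatty acid oxidation in 19 of 24 (0.0197), heat shock chaperones in 15 of 16 (0.0211) and immediate early genes in 11 of 16 (0.0439), with adjusted p from 0.528 to 0.691 with an estimated correlation. Aldh1a1 was at 463 ± 29.2 CPM in Het and 337 ± 35.9 CPM in Homo. Only the ribosomal and interferon calls held without each library in turn. The acute phase call ended without Het 2 (camera adjusted p = 0.507), cell cycle without Het 3 (0.167) or Homo 4 (0.421), xenobiotic without Homo 2 (0.12) and lymphocytes without Homo 1 (0.0778) or Homo 2 (0.0756). Without Het 2, Het 4, Homo 1 or Homo 2 the heat shock (highest 0.589) and fatty acid (0.202) calls ended. The heat shock list mean differed by -0.14, by -0.23 without Het 1, Het 3 or Homo 4, by -0.09 without Het 4 and by only -0.02 without Het 2. The fatty acid list mean differed by -0.14, and by -0.22 without Het 1 and -0.25 without Homo 4. It differed by -0.05 without Het 2 and by -0.08 without Homo 1 or Homo 2. The erythroid call ended without Het 2, Het 3 or Homo 1 (highest 0.0903). The macrophage call ended without WT 5, WT 6, Het 2, Het 4, Homo 1, Homo 2 or Homo 4 (highest 0.363), and the immediate early call without WT 1, WT 2, WT 5, Het 2, Het 3, Homo 1, Homo 2 or Homo 3 (highest 0.351).

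A trend over WT, Het and Homo was found for 30 genes, 21 rising and 9 falling, with 25 on chromosome 17. Of these, 21 rising and 8 falling genes were also called in Homo against WT. Per step of genotype Abca3 rose by log2 0.96, Tedc2 fell by 1.00 on the log2 scale, Riok2 fell by 0.49, Unkl by 0.40 and Pgap6 by 0.35 (edgeR adjusted p = 2.11e-07, 3.9e-06, 5.68e-06, 0.00334 and 0.0241). These slopes come from 1 straight line over the 3 groups, and the steps can be uneven. The slope of Pkd1 was -0.22 (edgeR adjusted p = 0.0468), with log2 differences of -0.11 in Het against WT and -0.35 in Homo against Het. Its trend call was not followed over the alternatives. The slopes of H2-Bl, Hmga1b, H2-T10 and H2-T24 were 1.61, 1.00, 0.82 and 0.78. H2-Bl was uneven, with log2 differences against WT of 2.85 in Het and 3.16 in Homo. Hmga1, the chromosome 17 parent of Hmga1b, was the falling gene called here and not in Homo against WT, at 13.0 ± 1.92, 8.39 ± 2.38 and 6.99 ± 1.23 CPM (edgeR adjusted p = 0.0486). The count was 19 without WT 1, 19 without WT 6, 55 with DESeq2 and 4 without chromosome 17 genes. Leaving out any 1 library except Homo 3 ended the trend call of at least 1 of H2-Bl, Hmga1b, H2-T10, H2-T24, Hmga1 and Pgap6, whose highest adjusted p over all alternatives were 0.404, 0.493, 0.162, 0.0866, 0.314 and 0.124.

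Over all genes tested, the log2 fold changes of Homo and Het against the shared WT libraries had a correlation of 0.387 across genes, which are not independent replicates. Simulated unchanged groups gave 0.388 ± 0.0155 (SD, 20 simulations). The covariance was 0.0381 against 0.0345 ± 0.00144 simulated (SD), a difference of 0.00354, and the sign was shared by 60.9% of genes against 60.3% simulated. With different WT libraries for each comparison, over 20 halvings, the mean correlation was 0.00526. Genes of chromosome 17 had a correlation of 0.788 and the rest 0.341. Without chromosome 17 genes the covariance was 0.0315, not above the value simulated over all genes. Their mean correlation over the halvings was -0.0483, so the excess was not seen off chromosome 17.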

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

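The tests of the dose, of the genome as a whole, of copies of chromosome 17 genes, of the pair Hmga1 and Hmga1b, and of neighbouring switched genes were chosen only after the result was seen, and those of the stretch, the splits, the clock and single libraries before.

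Of the 36 genes called in Homo against WT, 34 had a place, and 82.4% of those were on chromosome 17 against 4.82% of the genes tested (Fisher's exact p = 8.54e-32), which argues against lower Pkd1 acting evenly over the genome as the whole cause. The calls ran over a stretch of 477 tested genes, and 16% of its 449 uncalled genes had an unadjusted p under 0.05, against 4.23% on other chromosomes (Fisher's exact p = 4.99e-21). The median Het difference was 0.54 of the Homo difference over the 28 genes (95% bootstrap interval 0.461 to 0.606), although choosing genes on Homo can bias it. The bootstrap drew genes from the same animals, so its interval leaves out animal-to-animal variation. The Fisher tests of chromosome 17 likewise count genes as independent, and the ends of the stretch came from the calls. A candidate explanation, a hypothesis from the same data, is chromosome 17 sequence carried along with the mutant allele. The calls ran from place 4 to place 480 of 753, with Pkd1 at place 150, which argues against action on nearby genes as the whole cause. For genes close to Pkd1 such action is left open, and the ratio does not tell these explanations apart. Elsewhere, 66.7% of 6 called genes matched a chromosome 17 transcript, against 11.6% of 353 processed pseudogenes (Fisher's exact p = 0.00271). That p gives no support, since the matched genes bear the names of chromosome 17 genes and were seen before the test was chosen. The matches themselves, at 99.4% identity or more, mean that reads of chromosome 17 transcripts may be assigned to copies. For Hmga1 and Hmga1b this stays open: the log2 difference of their sum, -0.25 (14.3 to 12 CPM, exact permutation p = 0.0381), decides nothing, since parts that move in opposite directions must offset each other.

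The fatty acid oxidation list lay lower in Homo by -0.40 in mean log2 CPM. Without any 1 library the difference ran from -0.30 to -0.51, which argues against 1 library as its source. With a clock phase score as covariate it was -0.33 (SE 0.17), and since the bound for the clock was -0.20, the tables could not exclude another phase of the clock. The score differed by -0.43 between Homo and WT (exact permutation p = 0.324), and the genotype stays open as untested beside animal-to-animal variation.

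In 25 genes the libraries fell into an upper and a lower set at least 3 log2 units apart, none of them divided exactly by genotype. The search took genes with 2 to 12 upper libraries averaging at least 5 CPM. That floor leaves out Gm10499, at 0 in all WT libraries, and Gm13169, at 0 in all Homo libraries. Serpina3c was at 371 to 513 CPM in 6 libraries, 2 per group, and at most 2.39 CPM in the rest, and its pseudogene neighbour Gm8893 divided the libraries in the same way. Of 4 neighbouring pairs 25% shared a division, against 1.8% of 278 pairs on different chromosomes (Fisher's exact p = 0.0829), so a segregating strain background could neither be excluded nor shown with so few pairs. Across chromosomes, Rprl3, Rprl2 and Gm3375, on chromosomes 8, 3 and 7, shared a division. So did Gm42923 with Zfp872 and Gm53189 with Vcp-rs. No biological explanation was tested.

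Other splits of the libraries tested whether chance could give as many calls. Of 100 splits of the Homo and WT libraries, 1, the real one, called at least 36 genes, the highest other calling 4. That share lies below the bound set beforehand for chance, but only a sample of the possible splits was run. Of 100 splits of the Het and WT libraries, 3 called at least 9, a share below the bound set beforehand for chance. The highest other called 63, with WT 1, WT 2, Het 1 and Het 3 against the rest. A grouping that mixes the genotypes can thus give more calls than the real one, so the count alone does not exclude such a cause. What lies behind that split was not tested. Of 35 splits of Homo and Het, 2 called at least 5, the highest other calling 18, so chance was not excluded there. That other split set Het 2, Het 3, Het 4 and Homo 4, with clock phase scores of -1.86 to -1.58, against Het 1 and Homo 1 to Homo 3, with scores of -3.11 to -2.55, as seen after the count. Of 100 orders drawn for the trend, 1, the real one, called at least 30, the highest other calling 22. That share too lies below the bound for chance. Such splits cannot separate the genotype from a litter or batch, which the labels do not give.

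A library stood far from the others of its group in 30 of 480 groups of values tested, where chance gives about 1 in 20. In WT 1, Cd3e was at 3.93 CPM (others 12.6 to 14.2), Cd68 at 10.2, Pkd2 at 12.8 (others 19 to 22.3) and Naa12 at 52.2 CPM. In WT 3, Aldh1a1 was at 469 CPM and H2-T10 at 0.414 CPM. In WT 4, Fads2 was at 985 CPM (others 581 to 663), H2-Bl at 0.345 and Pgap6 at 12.8 CPM. In WT 5, Rnf39 was at 2.11 CPM and the immediate early list at a mean log2 CPM of 3.15. In WT 6, Gsta2 was at 2.9 CPM and the lipogenesis list at a mean log2 CPM of 7.8. In Het 1, Glo1 was at 428 CPM (others 264 to 277), C1qb at 34.1 and Meiob at 7.55 CPM. In Het 2, Cryab was at 1.27 CPM, Gbp2 at 4.59, Il1rn at 3.41 and Sqle at 99.6 CPM, and the acute phase list at a mean log2 CPM of 8.65. In Het 3, Fdps was at 183 CPM (others 231 to 241). In Homo 1, Mup7 was at 4890 CPM (others 9330 to 10400), Tsc2 at 37.1 CPM and the ATF4 list at a mean log2 CPM of 2.27. In Homo 4, Mt1 was at 65.5 CPM (others 7.49 to 8.78), Mt2 at 14, Alas2 at 46.8 and Cyp4a12b at 49.8 CPM, and the 10 most abundant genes took 23.1% of counts (others 20.2 to 20.5).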

How the results depend on the processing

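Leaving out chromosome 17 genes and the permutation of list means were chosen after the data had been seen. Counts of genes moved by over 1.5 times as follows, and the cause was not tested unless given. DESeq2 called 64 genes in Homo against WT, 35 in Het against WT, 22 in Homo against Het and 55 for the trend. Without a low-count filter Het against WT gave 23. In Het against WT, voom, robust edgeR, the library total only, the replicate block, 1 surrogate variable and the fit of 2 groups each called 1 lower gene. With only the 2 groups fitted, Homo against Het gave 2. Without chromosome 17 genes, which removes most calls by construction, the counts were 5, 4, 1 and 4. It also ended the calls of Hmga1b, Cyp4a12b and ENSMUSG00000121610 in Homo against WT, and that of Hmga1b for the trend. The replicate numbers did not pair the libraries: 2 of 12 pairs had a correlation over 0.1 (range -0.13 to 0.16, 2000 genes), and 4 of 12 libraries correlated best with their own number. With the replicate block the counts were 19 for Homo against WT, 2 for Homo against Het and 11 for the trend, and in Homo against WT it also ended the calls of Pla2g7, H2-T24 and Gfer (adjusted p at most 0.0773). In Het against WT the block ended the call of H2-Bl (adjusted p = 0.0793). The Pkd1 log2 fold change in Homo was -0.42 with the library total only (adjusted p = 0.0576), -0.45 with the replicate block (0.071) and -0.48 with 1 surrogate variable (0.0572), none past the threshold.

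Gene lists called numbered 0 in each of the 3 comparisons with an estimated correlation, 0 with fry and 0 by exact permutation of list means. The smallest p of that permutation is 0.0286 for 4 against 4 libraries and 0.00476 for 4 against 6. Over 28 lists this leaves little room to pass, and no list could pass alone in any of the 3 comparisons. Fry's test of change in either direction called 2 lists in Het against WT (cholesterol synthesis and stellate cells, adjusted p = 0.0265). Camera called 7 in Homo against Het with the strict filter. The correlation of fold changes was 0.41 with the strict filter and 0.00526 with different WT libraries for each comparison.

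Leaving out 1 library at a time gave 23 (without Homo 1) to 40 genes in Homo against WT, 8 to 11 in Het against WT, 4 to 7 in Homo against Het and 19 (without WT 1 or WT 6) to 33 for the trend. Lists ran from 9 to 12, from 5 (without WT 4) to 10 and from 6 (without Het 2 or Homo 1) to 13 in the 3 comparisons. The Pkd1 log2 fold change ran from -0.49 to -0.42 in Homo, past the threshold in 7 of 14 fits, and from -0.18 to -0.05 in Het. The correlation ran from 0.29 to 0.45. Pkd2 in Homo against Het ran from -0.035 (without Homo 2) to 0.50, and Cdkn1a in Homo against WT from -0.025 (without Homo 4) to 1.98.

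Over single named genes past the threshold, 279 results kept their side and direction and 54 lost the call, and 382 and 94 did so when 1 library was left out. Other scalings moved the median log2 fold change of all genes by at most 0.0631. The sex covariate was not run, since all libraries had Y-linked transcripts.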

Other observations

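The genes described here were picked after their values were seen.

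Rcan2 and Btbd9 of the chromosome 17 stretch also passed in Homo against WT. Rcan2, an inhibitor of calcineurin, rose from 3.15 ± 0.568 CPM in WT to 6.62 ± 2.02 CPM in Homo (SD), and Btbd9 from 18.7 ± 0.961 to 25.5 ± 0.882 CPM. Dnah8, next to Glo1 in the gene order and not called, stood at 0.333 ± 0.0991 CPM in WT, 0.822 ± 0.582 CPM in Het and 1.44 ± 0.734 CPM in Homo. ENSMUSG00000121779, called without a place in the annotation used, had 12.7 ± 2.66, 42.3 ± 2.23 and 75.2 ± 3.53 CPM.

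Some genes were near absent in part of the libraries, and those named here passed in none of the genotype comparisons or the trend. Of 2 entries with the symbol Nnt, ENSMUSG00000116207 was at 8.13 to 10.5 CPM in WT 1, WT 3, WT 5 and Het 3 and at 0 in the others, all 4 Homo libraries included. The other entry, ENSMUSG00000025453, averaged 33.8 ± 14.1 CPM in WT, 34.3 ± 10.7 CPM in Het and 38.6 ± 13.1 CPM in Homo. Gstp3 was at 243 to 300 CPM in WT 4, Het 3 and Homo 3 and at most 12.3 CPM elsewhere. In Homo 2 alone, C1rb was at 138 CPM, Mtcl1 at 21.7 and Scn8a at 11.8 CPM.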
